A study of Arabidopsis thaliana with 12 samples.

How the data were processed

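RNA sequencing compared transcript levels in rosette leaves of 4 Arabidopsis thaliana genotypes, with 3 libraries each. These were the wild type Col-0, the mutant ka120 in the Col-0 background, and the double mutants ka120 pad4 and ka120 ndr1. Per the labels' protocols, plants were grown in soil for 3 weeks at 22 °C with 16 h of light and 8 h of dark and were not treated. Strand-specific libraries were made from mRNA and sequenced as paired reads of 150 bases. Single pad4 and ndr1 mutants were not in the series, and the alleles, the sampling time and any batches are not given in the sources used here. Nothing in the labels says whether the 3 libraries of a genotype came from separate plants or pools, so p-values measure the spread between these samples.

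Per the submitters' processing notes, HISAT2 2.0.4, HTSeq 0.6.1p1 and TAIR10 were used; the role of each, the strand setting of the counting and the annotation release are not given in the sources used here. The deposited count table was taken to hold expected counts (estimated counts per gene and library), for 34262 genes. These values were already whole, with 0 values that were not, so rounding changed nothing. Between 45.7% and 48.1% of the values from 4 to 40 in each library were multiples of 4, against 25% by chance. The reason is not known, and how the totals relate to the number of sequenced fragments was not tested; which program made the table is unclear. The authors also deposited log2 values for 22605 genes. Each equalled the log2 of the raw count plus 0.5 over a constant per library, to a relative spread of at most 6.9e-09. The gene filter behind that table is not given in the sources used here, and the table served only for this check and for 1 alternative.

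Gene symbols and coordinates came from the TAIR10.1 reference. It matched 32548 of the identifiers and left 1714 unmatched, of which 1429 were Ensembl RNA genes. The table held 133 chloroplast and 152 mitochondrial genes, 0 lines that name no gene and 0 columns without a sample. The reference gives AT3G08960 no name, and the sources used here give KA120 no locus; that AT3G08960 is KA120 was taken from background knowledge. Reads shared between near-identical genes cannot be assigned with certainty, which affects the RPP4, RPP5 and SNC1 cluster, the RBCS and LHCB1 families and the 18S ribosomal RNA copies.

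Counts were tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16, with TMM factors and the default filter on low counts, which left 22351 genes. A single model with 1 coefficient per genotype was fitted to all 12 libraries and left 8 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed in each of 6 comparisons. These were ka120 against Col-0, each double mutant against ka120 and against Col-0, and the double mutants against each other. The double mutants share the ka120 libraries in 2 of the comparisons and the Col-0 libraries in 2 others, so overlaps between such lists are not independent. Levels are normalised counts (CPM, scaled to the effective library size), as mean ± SD of 3 libraries. Changes are log2 fold changes ± an approximate standard error, taken as the absolute log2 fold change over the square root of the F statistic. Gene lists were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01, on log2 CPM with a prior count of 2; lists with fewer than 5 tested members got values only.

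Lists of genes were written for salicylic acid (SA) synthesis and signalling, pathogenesis-related and SA marker genes, NLR immune receptors, pattern-triggered immunity, pipecolic acid, negative regulators of immunity, camalexin, jasmonate, protein folding in the endoplasmic reticulum (ER), heat shock, photosynthesis, senescence, anthocyanin, aliphatic glucosinolates, abscisic acid, cell wall growth, cell cycle, circadian clock, flowering, nuclear transport, guard cell, shoot meristem, root and reference genes, with the mutated loci apart. Named genes were picked by a rule. For each direction of the 4 main comparisons it took the 8 called genes with the largest fold, each with no overlap between the libraries of the 2 groups and a mean of at least 5 CPM in the higher group. For the double mutants against Col-0 it took 4 per direction. Of these, genes with a symbol are named below and the others are counted. From each list it took the 4 members with the largest change in ka120, and SNC1 in every case. These lists, this rule, the tests of the 6 comparisons and the other settings to try, apart from those given below as added, were chosen before the data were examined. Other list members, among them PR5, NUDT6 and many of the SA genes, are named as exceptions, as the few called ones or as examples, and all of these were chosen after their values were seen. Their calls were not followed under the other settings. Those settings covered only genes picked by the rule, and not in every comparison, so a call given without lost calls need not be stable.

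A ka120-changed gene counted as moved back when the double mutant differed from ka120 in the opposite direction with an adjusted p under 0.05. The slope of the double mutant's change on the ka120 change, both against Col-0, was taken by least squares through the origin over all ka120-changed genes, and both changes share the Col-0 libraries. For reference, libraries were redrawn from the fitted model 10 times with the double mutant set to the ka120 level or to the Col-0 level; such draws carry no variation shared between genes.

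The other settings were RLE and upper quartile factors, no filter beyond 1 count, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, organelle genes left out and counts thinned to the smallest total. DESeq2 1.42.0, a fit to only the 2 groups, a threshold of at least 2-fold, limma-trend on the deposited log2 values with pseudocounts of 1 and 0.1 (for ka120 against Col-0), camera with an estimated correlation, fry, and each replicate left out in turn completed them. Counts divided by 4, and genes at 0 in 1 library but at 5 CPM or more in another of the genotype left out, were added after seeing the data, as was the slope without genes that had no count in a genotype. The random seed was 20.

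The workflow was tested on simulated data with counts drawn at the measured depth and spread, for the comparison of ka120 with Col-0. With 200 changed genes, it called 64.2% of those changed 1.5-fold, 98.5% of those changed 2-fold and 98.5% of those changed 4-fold. Of 186 calls, 12 were on unchanged genes. In the same simulation, ka120 pad4 against ka120 was tested over the changed genes that had been called in ka120: 94.4% of 89 set back to the Col-0 level were called as moved back, and 0% of 85 kept at the ka120 level. Genes were drawn independently, and far fewer changed than in the data. The scaling with as many changed genes as in the data, and a partial return toward Col-0, were therefore not tested.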

Results

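Transcript levels were measured by RNA sequencing in 12 libraries of rosette leaves, 3 each from the wild type Col-0, the ka120 mutant and its double mutants with pad4 and with ndr1. KA120 belongs to the importin-beta family of nuclear transport receptors, and the study's title concerns its role in restraining effector-triggered immunity. PAD4 acts with EDS1 downstream of TIR-type NLR immune receptors, and NDR1 is needed by several NLRs of the coiled-coil type. The double mutants ask how far the ka120 state differs when either mutation is added. Total counts ran from 70386729 to 80707416 in Col-0, from 78305746 to 85884840 in ka120, from 71290882 to 71948016 in ka120 pad4 and from 68436911 to 81727498 in ka120 ndr1. Between 23074 and 24423 genes had a count in a library. Libraries of the same genotype correlated at 0.976 to 0.983, and libraries of different genotypes at 0.903 to 0.978. On the first principal component, with 54.5% of the variance, Col-0 stood at 1 end, ka120 at the other, and both double mutants between them, closer to ka120.

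The mutated loci showed which transcripts the labels could be checked against. KA120 (taken as AT3G08960, chromosome 3, 2729743 to 2737356 in TAIR10.1) had 29.2 ± 4.48 CPM in Col-0 and 5.28 ± 0.663 in ka120, 4.14 ± 0.615 in ka120 pad4 and 5.01 ± 0.430 in ka120 ndr1 (SD, n = 3). It fell by 2.47 ± 0.15 in ka120 (log2, adjusted p = 9.15e-08), and each of the 9 mutant libraries had fewer counts than each Col-0 library. NDR1 (AT3G20600, chromosome 3, 7194771 to 7195769) had 5.27 ± 0.433 CPM in Col-0 and 13.1 ± 1.52 in ka120, but 0, 12 and 8 counts in the 3 ka120 ndr1 libraries (log2 fold change against ka120 -7.27 ± 0.43, adjusted p = 6.68e-06). PAD4 (AT3G52430, chromosome 3, 19431095 to 19434450) rose from 5.13 ± 0.482 CPM in Col-0 to 85.1 ± 27.1 in ka120 (4.05 ± 0.34, adjusted p = 1.26e-06). In ka120 pad4 its transcript stood at 12.7 ± 5.82 CPM, above Col-0 (1.303 ± 0.32, adjusted p = 0.00625). Its level therefore does not check that label. The allele is not known.

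**Figure D1:**
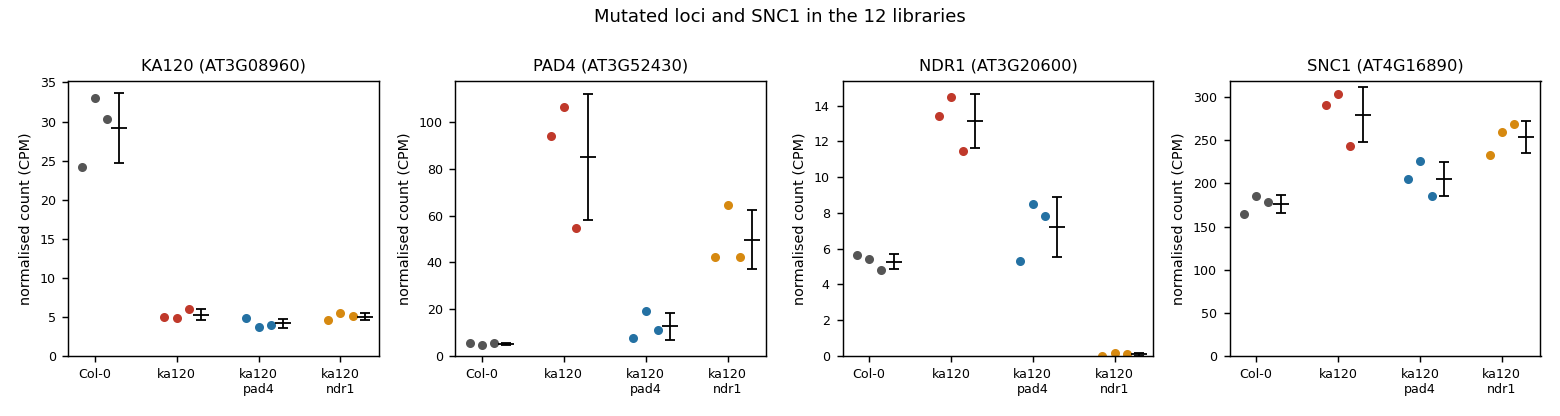
Normalised counts (CPM, vertical axes) of KA120, PAD4, NDR1 and SNC1 in the 4 genotypes, with 1 point per library and the mean ± SD of 3 libraries beside the points. KA120 was low in all mutant genotypes, NDR1 was near 0 in ka120 ndr1, and PAD4 in ka120 pad4 had a mean of 12.7 CPM.

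The comparison of ka120 with Col-0 asked what the ka120 mutation alone changed in leaves. PR1 (AT2G14610, chromosome 2, 6241640 to 6242541), the usual marker of salicylic acid (SA) responses, had 0, 4 and 0 counts in the Col-0 libraries and 1689 ± 304 CPM in ka120. BGL2 (PR2), a glucanase induced with it, rose from 4.64 ± 0.555 to 850 ± 168 CPM (7.52 ± 0.41, adjusted p = 5.85e-08). DMR6, an SA hydroxylase, rose from 9.23 ± 1.68 to 440 ± 116 CPM (5.58 ± 0.32), and BIP3, a stress-induced chaperone of the endoplasmic reticulum (ER), from 0.880 ± 0.219 to 189 ± 36.3 CPM (7.73 ± 0.51). LHCB2.3, a light-harvesting protein, fell from 1832 ± 163 to 482 ± 108 CPM (-1.93 ± 0.21). In all, 12276 of 22351 tested genes changed, 6252 higher and 6024 lower, and 4060 of them by at least 2-fold.

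All 14 pathogenesis-related and SA marker genes rose, as did 14 of them adjusted over the list alone. AIG1 (7.66 ± 0.57), PNP-A (7.09 ± 0.46) and PR5 (5.24 ± 0.29) were among them. The list passed camera (adjusted p = 1.16e-08) but not with an estimated correlation (adjusted p = 0.35 with an estimated correlation). Of 24 tested genes of SA synthesis and signalling, 20 rose over all genes and 20 adjusted over the list alone. They included EDS16 (ICS1), the synthase that makes the SA precursor isochorismate (3.08 ± 0.31), the transporter EDS5 (3.45 ± 0.22), PBS3 (4.28 ± 0.45) and the regulators SARD1 (4.64 ± 0.36) and CBP60G (4.49 ± 0.39). EDS1, the partner of PAD4, rose by 2.34 ± 0.32, while ICS2 (-2.37 ± 0.40) and UGT74F1, an SA glucosyltransferase (-0.66 ± 0.24), fell, and 3 fell adjusted over the list alone. This list had adjusted p = 1.7e-06 by camera and adjusted p = 0.382 with an estimated correlation.

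Among 30 tested NLR immune receptors, 25 rose and 1 fell, and 26 rose and 1 fell adjusted over the list alone. The helper receptor ADR1-L1 rose from 24.4 ± 2.91 to 193 ± 31.9 CPM (2.99 ± 0.19), ADR1-L2 by 2.79 ± 0.14 and AT5G41750 (SSI4) by 4.86 ± 0.32. SNC1 (AT4G16890, chromosome 4, 9500271 to 9505972) rose by 0.67 ± 0.10 (adjusted p = 8.89e-05), from 176 ± 10.4 to 280 ± 31.8 CPM, and its neighbour AT4G16880 fell by 1.36 ± 0.16. The camera test of the list gave adjusted p = 3.01e-08, and adjusted p = 0.35 with an estimated correlation. Pattern-triggered immunity genes rose in 25 of 34 tested cases and 25 adjusted over the list alone, with the largest fold for YLS9 (NHL10), at 0 CPM in Col-0 and 1.01 ± 0.408 in ka120, followed by the kinases CRK6 (5.78 ± 0.42), FRK1 (5.25 ± 0.70) and ARCK1 (CRK45, 5.12 ± 0.54). RBOH F, an oxidase of the respiratory burst, fell (-0.53 ± 0.12), and 2 fell adjusted over the list alone (camera adjusted p = 1.62e-07, adjusted p = 0.35 with an estimated correlation).

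Genes of pipecolic acid and systemic acquired resistance rose in 6 of 7 tested cases, and 7 adjusted over the list alone. ALD1, the first enzyme of pipecolic acid synthesis, went from 0.0225 ± 0.0389 to 3.75 ± 1.53 CPM, and FMO1, which hydroxylates pipecolic acid, from 0.0236 ± 0.0409 to 4.27 ± 1.38 CPM. The list had adjusted p = 6.55e-04 by camera and adjusted p = 0.35 with an estimated correlation. Of 10 negative regulators of immunity, 8 rose and 9 rose adjusted over the list alone, among them BON3 (5.33 ± 0.34), BAP2 (5.49 ± 0.59) and NUDT7 (2.42 ± 0.28); camera gave adjusted p = 6.55e-04, and adjusted p = 0.35 with an estimated correlation. All 14 genes of ER protein folding rose, and 14 adjusted over the list alone, including the disulfide isomerases PDIL1-2 (2.82 ± 0.23) and PDIL1-1 (2.71 ± 0.23) and the calreticulin CRT3 (2.56 ± 0.25). Their list had adjusted p = 1.94e-08 by camera and adjusted p = 0.35 with an estimated correlation.

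All 30 photosynthesis genes fell, and 30 adjusted over the list alone, with PSBQ-2 of photosystem II at -1.76 ± 0.15 and GAPB of the Calvin cycle at -1.46 ± 0.07. The list's share of all counts was 15.7% to 16.6% in Col-0 and 9.53% to 10.7% in ka120. RBCS1B, a small subunit of Rubisco, fell by 1.40 (adjusted p = 0.0279), a call that ended without Col-0 replicate 2 (0.124) and without ka120 replicate 1 (0.103) or 2 (0.102). Camera gave adjusted p = 1.82e-15 for photosynthesis, and adjusted p = 0.35 with an estimated correlation. Among 19 genes of abscisic acid, drought and cold, 10 fell and LTI65 (RD29B) rose by 2.06 ± 0.44, and the counts were 10 and 1 adjusted over the list alone. COR15A, a chloroplast protein of cold tolerance, fell from 16.9 ± 3.46 to 0.246 ± 0.113 CPM (-6.10 ± 0.49), and RAB18 (AT5G66400) by 1.44 ± 0.18; camera gave adjusted p = 0.0129, and adjusted p = 0.382 with an estimated correlation. Aliphatic glucosinolate genes fell in 9 of 14 cases and 9 adjusted over the list alone, with the regulators MYB29 (-1.26 ± 0.12) and MYB28 (-0.86 ± 0.08) among them, while CYP79F2 rose by 0.43 ± 0.15. That list had adjusted p = 0.00622 by camera and adjusted p = 0.638 with an estimated correlation.

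The other lists did not pass camera in ka120. Of 14 camalexin and indole glucosinolate genes, 7 rose, including CYP71A12 (6.80 ± 0.79), CYP71A13 (4.64 ± 0.72) and PAD3 (4.06 ± 0.99) of camalexin synthesis, and 3 fell, MYB34, CYP79B3 and PEN2 (AT2G44490), the first a regulator of indole glucosinolates (adjusted p = 0.24; 8 and 3 adjusted over the list alone). Of 26 jasmonate and ethylene genes, 4 rose and 10 fell, also adjusted over the list alone, with JAZ1, LOX4 and JAR1 among the higher, the storage protein VSP2 at -3.87 ± 0.41, the synthesis enzyme AOS at -2.62 ± 0.27 and the acetyltransferase NATA1 at 7.10 ± 0.94 (adjusted p = 0.539). Heat shock genes rose in 4 of 11 cases, HSP17.4 (2.86 ± 0.60), HSP17.6A, HSP90.1 (1.80 ± 0.15) and MBF1C, and HSP18.2 fell by 2.29 ± 0.43; the counts adjusted over the list alone were 4 and 1 (adjusted p = 0.598, median -0.01, mean 0.59). Senescence genes rose in 4 of 10 cases, BCB (2.98 ± 0.24), WRKY6, NYE1 and NYC1, and fell in 2, SAG29 (-2.56 ± 0.41) and NAP, with 4 and 2 adjusted over the list alone (adjusted p = 0.643). Anthocyanin genes rose in 3 of 15 cases, the regulators MYB90 (2.98 ± 0.44), PAP1 (AT1G56650, 1.18 ± 0.33) and MYB111 (0.97 ± 0.17), and fell in 3, the enzyme genes UF3GT, TT5 and F3H (3 and 2 adjusted over the list alone, adjusted p = 0.988, median -0.01, mean 0.21, camera direction lower). The call of UF3GT (adjusted p = 0.0188) ended without Col-0 replicate 3 (0.0535) and without ka120 replicate 1 (0.0775) or 2 (0.0735).

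Among 13 circadian clock genes, 3 rose, GI (1.04 ± 0.10), ELF3 and TOC1, and 5 fell, the morning gene CCA1 (-0.86 ± 0.07), RVE8, TCP11 (CHE), LHY and PCL1 (LUX), also adjusted over the list alone (adjusted p = 0.643). Floral organ genes rose in 4 of 11 cases, SEP2 (AT3G02310, 2.66 ± 0.70), PI (1.47 ± 0.42), AG (1.45 ± 0.26) and AGL8 (FUL, 1.34 ± 0.18), and AGL20 (SOC1) fell, with 4 and 1 adjusted over the list alone (adjusted p = 0.402); PI had adjusted p = 0.0104, and 0.0579 without ka120 replicate 1. Of 21 cell cycle genes, 7 rose, with the replication gene MCM4 at 0.57 ± 0.07, and CDKB2;1 fell by 0.54 ± 0.14 (7 and 1 adjusted over the list alone, adjusted p = 0.219). Cell wall growth genes rose in 4 of 10 cases, IAA19 (0.96 ± 0.15), XTH24, IAA29 and EXPA10, and fell in 4, the expansins EXPA11 (-1.41 ± 0.23), EXPA5 and EXPA8 and XTH4 (4 and 4 adjusted over the list alone, adjusted p = 0.809). Markers of guard cell, epidermis and vasculature fell in 6 of 11 cases, among them SUC2 of the phloem and KCS6 (CER6) of wax synthesis (-0.46 ± 0.07), with 6 adjusted over the list alone (adjusted p = 0.0863). HT1, 1 of these 6, had adjusted p = 0.0329, and lost the call without Col-0 replicate 1 (0.0772) or 2 (0.08) and without ka120 replicate 1 (0.13) or 2 (0.0937), as well as with the replicate number as a block (0.0522) and in a fit to only the 2 groups (0.0635).

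Among 20 nuclear transport genes 7 rose, with the importin-alpha MOS6 at 0.55 ± 0.12, and 5 fell, the importin-beta relatives SAD2 (-0.51 ± 0.06) and emb2734 (KETCH1, -0.51 ± 0.07), AT5G53480, IMPA-4 and IMPA-1; counts were 7 and 5 adjusted over the list alone (adjusted p = 0.623). Of 5 tested shoot meristem genes, only the receptor CLV1 changed (-0.76 ± 0.14), also adjusted over the list alone (adjusted p = 0.856, median 0.09, mean -0.47). Of 3 tested root genes, WOX5 rose by 3.73 ± 0.82, and 1 rose adjusted over the list alone. Of 7 reference genes, AT4G34270 (0.34 ± 0.09) and GAPC1 (0.32 ± 0.05) rose while PP2AA3 (-0.64 ± 0.06) and ACT2 (-0.42 ± 0.06) fell, with 2 and 2 adjusted over the list alone.

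Of the other members with the largest changes in these lists, WRKY38 (from 0 to 5.40 ± 3.37 CPM), UGT76B1, AT4G10500 (7.89 ± 0.77), WRKY62 (a mean of 0.3748 CPM in ka120), GRX480 (6.10 ± 1.03), BAP1 (5.05 ± 0.63), AT4G16960 (2.29 ± 0.22), GSTF6 (2.11 ± 0.22), MCM3 (0.49 ± 0.09) and CPR5 (0.34 ± 0.08) rose. PDF1.2c (-3.71 ± 0.94) and FMO GS-OX1 (-0.83 ± 0.15) fell. BSMT1, HAI2, CYCB2;1, SEN1 (AT4G35770), ELF4, BOA, AP3, APL, CLV3, KNAT1, STM, SHV2 and SHR did not pass, with adjusted p from 0.068 for KNAT1 to 0.663 for SHR.

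Of the 8 largest increases, PR1 had 4 counts in Col-0 and the other 7 genes had none there. The receptor-like protein RLP28 had 10.7 ± 1.37 CPM in ka120, LUP5, related to triterpene synthases, 10.6 ± 1.35, and the ATPase gene AATP1 7.88 ± 3.11. Besides PR1, the other 4 of the top 8 had no symbol. Among the 8 with the largest decrease, COR15A and MES18 (-5.30 ± 0.59, from 30.3 ± 5.97 to 0.768 ± 0.663 CPM) had a symbol and 6 had none. The test was the edgeR fit to 12 libraries, and 13308 genes had an unadjusted p under 0.05. Because 54.9% of the tested genes changed, each value is relative to the bulk of the transcriptome.

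**Figure D2:**
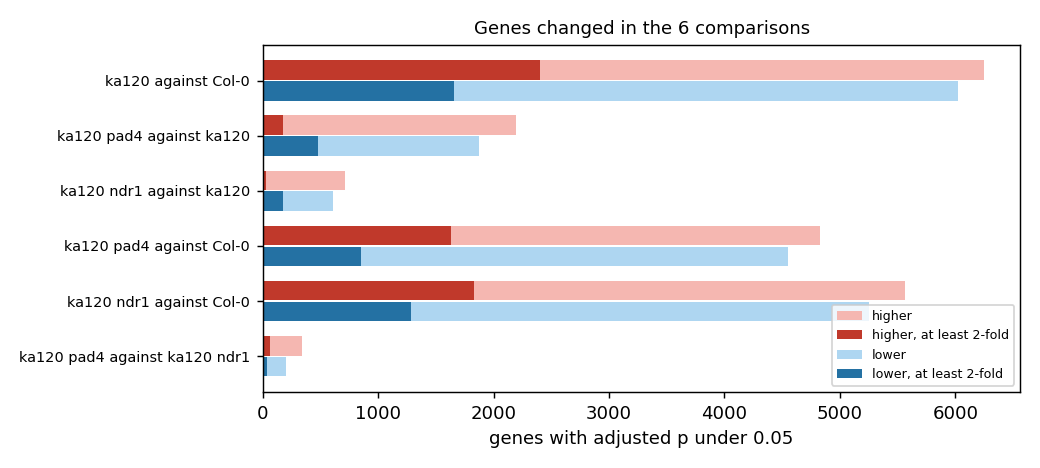
Number of genes (horizontal axis) higher or lower with an adjusted p under 0.05 in each of the 6 comparisons, with the part changed by at least 2-fold in a darker shade. The count was 12276 for ka120 against Col-0 and 535 between the double mutants.

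The comparison of ka120 pad4 with ka120 asked which ka120 changes were weaker with the pad4 mutation added. PR1 had 371 ± 241 CPM against 1689 ± 304 (-2.19 ± 0.39, adjusted p = 0.00343), BGL2 231 ± 137 against 850 ± 168 (-1.88 ± 0.32), and DMR6 175 ± 64.4 against 440 ± 116 (-1.33 ± 0.27). ARD3, an enzyme of the methionine salvage cycle, fell from 89.9 ± 15.5 to 10.6 ± 10.6 CPM (-3.08 ± 0.54), and CRK13, a receptor-like kinase, by 2.80 ± 0.34. MYB29 of the glucosinolate pathway rose from 21.3 ± 3.00 to 41.4 ± 6.66 CPM (0.96 ± 0.12).

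In this comparison 13 of 14 ER folding genes fell, and 14 adjusted over the list alone, with PDIL1-1 at -1.02 ± 0.22 (camera adjusted p = 2.48e-08, adjusted p = 0.369 with an estimated correlation). NLR receptors fell in 19 of 30 cases and 22 adjusted over the list alone, with ADR1-L1 at -0.83 ± 0.18 and SNC1 at -0.45 ± 0.10 (camera adjusted p = 1.46e-08, adjusted p = 0.369 with an estimated correlation). Of 24 SA genes, 15 fell, including PBS3 (-2.25 ± 0.41), EDS5 (-1.52 ± 0.20) and EDS16 (-1.40 ± 0.29), and adjusted over the list alone 17 fell and 1 rose (camera adjusted p = 3.52e-07, adjusted p = 0.369 with an estimated correlation). Of the 14 pathogenesis-related and SA marker genes, 8 fell, such as NUDT6 (-2.69 ± 0.35) and AIG1 (-2.60 ± 0.44), with 9 lower and 1 higher adjusted over the list alone (camera adjusted p = 4.93e-05, adjusted p = 0.369 with an estimated correlation). Pattern-triggered immunity genes fell in 12 of 34 cases and RBOHD rose by 0.26 ± 0.08, with 18 and 1 adjusted over the list alone (camera adjusted p = 4.47e-05, adjusted p = 0.369 with an estimated correlation). Negative regulators of immunity fell in 6 of 10 cases and 7 adjusted over the list alone, BON3 by 1.51 ± 0.26 (camera adjusted p = 6.3e-05, adjusted p = 0.369 with an estimated correlation). The pipecolic acid and systemic acquired resistance list did not pass: 1 of its 7 genes fell, AT5G52810 (SARD4), and 3 adjusted over the list alone (camera adjusted p = 0.0701). In the senescence list 5 of 10 fell, NAP, BCB (-1.23 ± 0.22), NYE1, NYC1 and WRKY6, and 6 adjusted over the list alone (camera adjusted p = 0.00621, adjusted p = 0.369 with an estimated correlation). Its exception SAG29 rose by 1.34 ± 0.40 (adjusted p = 0.0378), but not without ka120 replicate 1 (0.123) or 2 (0.132), nor without ka120 pad4 replicate 1 (0.0655), 2 (0.0985) or 3 (0.0655), nor in a fit to only the 2 groups (0.0909). WRKY6 (-0.60 ± 0.17, adjusted p = 0.0283) did not pass without ka120 replicate 1 (0.103) or 2 (0.136) or ka120 pad4 replicate 1 (0.0907) or 3 (0.0731), nor in a fit to only the 2 groups (0.0794).

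Higher in ka120 pad4 were 13 of 14 aliphatic glucosinolate genes, also 13 adjusted over the list alone, with MAM1, which lengthens the side chain, at 0.81 ± 0.13 (camera adjusted p = 4.79e-10, adjusted p = 0.369 with an estimated correlation). Photosynthesis genes rose in 15 of 30 cases and 19 adjusted over the list alone, GAPB by 0.47 ± 0.07 (camera adjusted p = 4.32e-08, adjusted p = 0.369 with an estimated correlation). Anthocyanin genes rose in 7 of 15 cases and 9 adjusted over the list alone, including the enzymes F3H (0.99 ± 0.13), TT4 (chalcone synthase, 0.83 ± 0.16) and DFR (0.68 ± 0.16). Their list had adjusted p = 5.5e-06 by camera and adjusted p = 0.369 with an estimated correlation. XTH31, a cell wall enzyme, rose from 8.30 ± 2.98 to 35.1 ± 13.4 CPM (2.08 ± 0.28) and was the only 1 of the 8 largest increases with a symbol. Among the 8 largest decreases, AATP1 (from 7.88 ± 3.11 to 0.273 ± 0.0728 CPM, -4.84 ± 0.35), the transcription factor gene WRKY38 (from 5.40 ± 3.37 to 0.248 ± 0.310 CPM) and HIPP22, a metal-binding protein (-4.39 ± 0.60), had a symbol and 5 had none.

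In total 4072 genes changed between ka120 pad4 and ka120, 2196 higher and 1876 lower, with 661 at least 2-fold, 178 of them higher and 483 lower. The count depended on single libraries: it was 2205 without ka120 replicate 1, 1885 without ka120 replicate 2, 2400 without ka120 pad4 replicate 1 and 2415 without ka120 pad4 replicate 3. A fit to only the 2 groups gave 2634. Of the genes picked by the rule, 24 lost the call in this comparison under at least 1 other setting, SAG29 and WRKY6 among them. Others were the immune genes BAP2, NUDT7, ADR1-L2, AT5G41750, AT4G16960, CRK6 and ARCK1 and the ER folding genes BIP3, PDIL1-2 and CRT3. NUDT7, for example, went from adjusted p = 0.0276 to 0.106 without ka120 replicate 2.

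The comparison of ka120 ndr1 with ka120 asked the same for ndr1. PR1 had 560 ± 112 CPM against 1689 ± 304 (-1.59 ± 0.38, adjusted p = 0.0328), and BGL2 350 ± 56.9 against 850 ± 168 (-1.28 ± 0.31, adjusted p = 0.0351). NUDT6 (-1.48 ± 0.33), SAG13 (-1.96 ± 0.43) and EDS5 (-0.99 ± 0.20) fell as well, and MAF5, a repressor of flowering, fell from 8.21 ± 0.550 to 2.46 ± 0.753 CPM (-1.74 ± 0.20, adjusted p = 0.0021). DMR6 did not pass (338 ± 83.6 against 440 ± 116 CPM, adjusted p = 0.416). The call of PR1 ended without ka120 replicate 1 (0.0989) or 2 (0.135) and without ka120 ndr1 replicate 1 (0.119), 2 (0.0646) or 3 (0.101). That of BGL2 ended without the same libraries (0.123, 0.138, 0.126, 0.0662 and 0.105). The calls of NUDT6, SAG13, EDS5 and MAF5 in this comparison were not followed under the other settings.

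Pathogenesis-related and SA marker genes fell in 6 of 14 cases and 7 adjusted over the list alone (camera adjusted p = 2.05e-05, adjusted p = 0.566 with an estimated correlation). Besides PR1 and BGL2, PNP-A of this list (adjusted p = 0.0483) lost its call without ka120 replicate 1 (0.163) or 2 (0.177). It also did so without ka120 ndr1 replicate 1 (0.173), 2 (0.0655) or 3 (0.134) and with no filter (0.057). Senescence genes fell in 4 of 10 cases and 6 adjusted over the list alone, the regulator NAP (-1.52 ± 0.27), BCB (-0.93 ± 0.22), WRKY6 (-0.88 ± 0.17) and ACD1 (camera adjusted p = 1.78e-04, adjusted p = 0.353 with an estimated correlation). Aliphatic glucosinolate genes rose in 5 of 14 cases, IMS2, SOT17, MYB29 (0.58 ± 0.12), AT2G31790 and CYP83A1, and 12 adjusted over the list alone (camera adjusted p = 8.24e-07, adjusted p = 0.566 with an estimated correlation). Photosynthesis genes rose in 3 of 30 cases, LHCB4.2, LHCB4.1 and LHCA4, and 11 adjusted over the list alone (camera adjusted p = 9.16e-07, adjusted p = 0.566 with an estimated correlation). Of 14 ER folding genes, only the calreticulin CRT1a fell over all genes (-0.40 ± 0.10), and 13 fell adjusted over the list alone (camera adjusted p = 2.4e-05, adjusted p = 0.566 with an estimated correlation). NLR receptors fell in 2 of 30 cases, ADR1 and RPP1, and 5 adjusted over the list alone (camera adjusted p = 0.00124, adjusted p = 0.566 with an estimated correlation). SNC1 did not pass (-0.14 ± 0.10, adjusted p = 0.422). The calls of BCB, WRKY6 and MYB29 ended without ka120 replicate 1 (0.112, 0.0745 and 0.0744), without ka120 replicate 2 (0.147, 0.0826 and 0.0924) and without ka120 ndr1 replicate 1 (0.125, 0.0564 and 0.0802). Those of WRKY6 and MYB29 also ended without ka120 ndr1 replicate 2 (0.0558 and 0.0536), and that of BCB without replicate 3 (0.0905).

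Of the pattern-triggered immunity genes, only WRKY60 fell (-0.73 ± 0.20), and 0 adjusted over the list alone (camera adjusted p = 0.00237, adjusted p = 0.566 with an estimated correlation). Of the SA genes, EDS5 alone fell, with 1 adjusted over the list alone (camera adjusted p = 0.0129, adjusted p = 0.589 with an estimated correlation). The abscisic acid list passed camera as lower with 0 called members, also adjusted over the list alone (adjusted p = 0.00104, adjusted p = 0.566 with an estimated correlation), and the cell cycle list as higher with 0 called members (adjusted p = 0.00295, adjusted p = 0.566 with an estimated correlation). In the anthocyanin list only MYB90, which switches on anthocyanin genes, fell (-2.04 ± 0.41, adjusted p = 0.0187), and 1 adjusted over the list alone (camera adjusted p = 0.0463, adjusted p = 0.589 with an estimated correlation). MYB90 lost its call without ka120 replicate 1 (0.0577) or 2 (0.0658) and without ka120 ndr1 replicate 1 (0.0654) or 2 (0.0523).

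Among the 8 largest increases, 3 genes had a symbol, RABA6b, a GTPase gene (1.39 ± 0.30, adjusted p = 0.025), CYP707A3, which breaks down abscisic acid (1.25 ± 0.24, adjusted p = 0.0166), and XTH15 (1.24 ± 0.28, adjusted p = 0.0274), and 5 had none. Without ka120 replicate 1 their adjusted p was 0.105, 0.0716 and 0.114, without ka120 replicate 2 it was 0.122, 0.0784 and 0.124, and without ka120 ndr1 replicate 1 it was 0.0645, 0.0511 and 0.081. RABA6b also lost the call without ka120 ndr1 replicate 2 (0.0714) or 3 (0.0626), CYP707A3 without replicate 2 (0.0545) and XTH15 without replicate 3 (0.0862). Among the 8 largest decreases, NDR1 and MIR2936 had a symbol and 6 had none. Of the 6, AT2G01010 and AT2G01020 are ribosomal RNA features. ENSRNA049494585 and ENSRNA049494515 are Ensembl RNA genes, and AT3G06355 is a non-coding RNA. These calls concern RNA other than mRNA. All but AT2G01010 of these 5 lost the call without ka120 ndr1 replicate 1 (0.0565 for AT2G01020, 0.0696 for ENSRNA049494585, 0.0652 for ENSRNA049494515 and 0.0516 for AT3G06355). ENSRNA049494585 and ENSRNA049494515 also lost it without ka120 replicate 1 (0.0546 and 0.0511) or 2 (0.0532 and 0.0502), and the first without ka120 ndr1 replicate 2 (0.0501). MIR2936 (adjusted p = 0.0443) rested on ka120 replicate 1, with 34.15 CPM there and 0.948 and 0.523 in the other ka120 libraries: without it the log2 fold change went from -4.855 to -0.845 (adjusted p = 0.398). Its call also ended without ka120 replicate 2 (0.0559) or ka120 ndr1 replicate 1 (0.149), 2 (0.106) or 3 (0.125), with no filter (0.0527), with the replicate number as a block (0.131) and in a fit to only the 2 groups (0.105).

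In total 1327 genes changed between ka120 ndr1 and ka120, 715 higher and 612 lower, and 5229 had an unadjusted p under 0.05. At least 2-fold were 207, 31 of them higher and 176 lower. The count fell to 148 without ka120 replicate 1, 136 without ka120 replicate 2, 211 without ka120 ndr1 replicate 1, 459 without replicate 2 and 725 without replicate 3, and was 2232 without ka120 replicate 3. DESeq2 gave 2576.

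**Figure D3:**
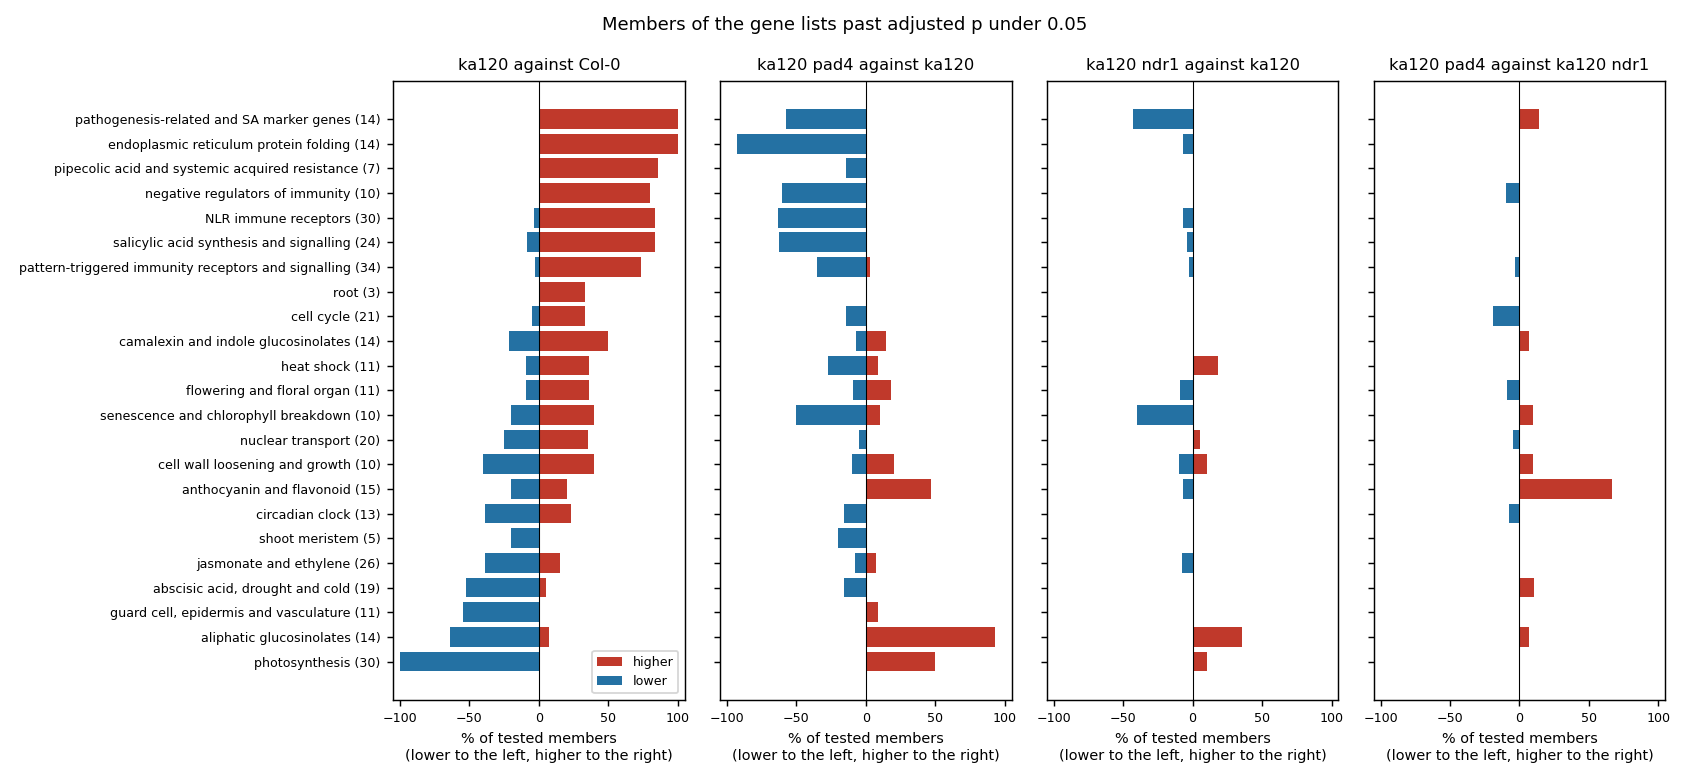
Percent of the tested members of each gene list (horizontal axis) that were higher or lower in 4 comparisons, with 1 bar per list and direction. In ka120, 14 of 14 ER folding genes rose and 30 of 30 photosynthesis genes fell (adjusted p = 0.35 with an estimated correlation for either list).

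Each double mutant was also compared with Col-0. Of the 6252 genes higher in ka120, 4229 were higher in ka120 pad4 and 4816 in ka120 ndr1 as well, and of the 6024 lower, 3984 and 4544. In draws with the double mutant set to the Col-0 level, a mean of 0.2 genes for ka120 pad4 and 0 for ka120 ndr1 were called against Col-0 at all. Independent lists would share 1351, 1557, 1225 and 1416, and part of the excess may come from the shared Col-0 libraries. PR1 stood at 371 ± 241 CPM in ka120 pad4 and 560 ± 112 in ka120 ndr1, against 0, 4 and 0 counts in Col-0. BGL2 was higher by 5.64 ± 0.38 and 6.24 ± 0.39, DMR6 by 4.25 ± 0.30 and 5.20 ± 0.32, and LHCB2.3 was lower at -1.65 ± 0.21 and -1.46 ± 0.21. COR15A was lower at -4.97 ± 0.46 and -7.57 ± 0.56. SNC1 did not pass in ka120 pad4 (0.22 ± 0.10, adjusted p = 0.0841) but rose in ka120 ndr1 (0.53 ± 0.10, adjusted p = 6.95e-04); between the 2 the difference did not pass (-0.31 ± 0.10, adjusted p = 0.117). PR1 and 3 genes without a symbol made up the 4 largest increases in each. COR15A and 3 genes without a symbol had the 4 largest decreases in ka120 pad4, and COR15A, NDR1 and 2 without a symbol in ka120 ndr1.

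In ka120 pad4 against Col-0, 9378 genes changed (4831 higher, 4547 lower, 2482 at least 2-fold). All 14 pathogenesis-related and SA marker genes rose, and 14 adjusted over the list alone (camera adjusted p = 1.16e-09, adjusted p = 0.402 with an estimated correlation). So did 14 of 14 ER folding genes, and 14 adjusted over the list alone (camera adjusted p = 9.05e-08, adjusted p = 0.402 with an estimated correlation). Photosynthesis genes fell in 28 of 30 cases and 28 adjusted over the list alone (camera adjusted p = 9.64e-17, adjusted p = 0.402 with an estimated correlation). SA genes rose in 18 of 24 cases, with ICS2 lower, and 19 rose and 3 fell adjusted over the list alone (camera adjusted p = 4.87e-05, adjusted p = 0.467 with an estimated correlation). NLR receptors rose in 22 of 30 cases, with AT4G16880 and RPP5 lower, and 23 and 2 adjusted over the list alone (camera adjusted p = 5.24e-06, adjusted p = 0.467 with an estimated correlation). Anthocyanin genes rose in 10 of 15 cases and 10 adjusted over the list alone (camera adjusted p = 0.00178, adjusted p = 0.467 with an estimated correlation), with MYB90 at 3.57 ± 0.45. The lists of pattern-triggered immunity, pipecolic acid, negative regulators and abscisic acid also passed camera (adjusted p from 1.24e-06 to 0.0127), and each lost the call (adjusted p = 0.402 to 0.467 with an estimated correlation).

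In ka120 ndr1 against Col-0, 10822 genes changed (5568 higher, 5254 lower, 3117 at least 2-fold). Pathogenesis-related and SA marker genes rose in 13 of 14 cases and 13 adjusted over the list alone (camera adjusted p = 2.22e-08, adjusted p = 0.323 with an estimated correlation). ER folding genes rose in 14 of 14, and 14 adjusted over the list alone (camera adjusted p = 4.07e-08, adjusted p = 0.323 with an estimated correlation). All 30 photosynthesis genes fell, and 30 adjusted over the list alone (camera adjusted p = 9.17e-16, adjusted p = 0.323 with an estimated correlation). SA genes rose in 20 of 24 cases, with ICS2 and EPS1 lower, and 20 and 2 adjusted over the list alone (camera adjusted p = 1.34e-06, adjusted p = 0.356 with an estimated correlation). Cell cycle genes rose in 10 of 21 cases, with CDKB2;1 lower, and 10 and 1 adjusted over the list alone (camera adjusted p = 0.00985, adjusted p = 0.578 with an estimated correlation), with MCM4 at 0.73 ± 0.07. Abscisic acid genes fell in 12 of 19 cases, and adjusted over the list alone 14 fell and 1 rose (camera adjusted p = 5.11e-05, adjusted p = 0.323 with an estimated correlation). The lists of pattern-triggered immunity, NLR receptors, pipecolic acid and negative regulators passed as well (adjusted p from 8.63e-08 to 6.65e-04), and each lost the call (adjusted p = 0.323 to 0.333 with an estimated correlation).

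Of the 12276 genes changed in ka120, 3449 (28.1%) moved back in ka120 pad4 and 1025 (8.35%) in ka120 ndr1, and 781 did in both. Of those in ka120 pad4, 1588 had been higher and 1861 lower in ka120, and 1345 no longer passed the test against Col-0. Libraries redrawn at the ka120 level gave a share of 0%, and libraries redrawn at the Col-0 level gave 88.5% for ka120 pad4 and 88.4% for ka120 ndr1. Taken over all ka120-changed genes, the slope of the fitted change on that of ka120 was 0.721 in ka120 pad4 and 0.807 in ka120 ndr1, against 0.972 for draws at the ka120 level. Per library the slope was 0.585, 0.770 and 0.679 in ka120 pad4 and 0.742, 0.827 and 0.783 in ka120 ndr1. These values per library came from log2 CPM with a prior count of 2 for both changes, so they need not average to the fitted slopes. The difference between the 2 fitted slopes was not tested. The share for ka120 pad4 was 17.5% without ka120 replicate 1, 15.1% without ka120 replicate 2, 16.4% without ka120 pad4 replicate 1 and 17.3% without ka120 pad4 replicate 3. For ka120 ndr1 it was 0.988%, 0.918% and 15.6% without ka120 replicates 1, 2 and 3, and 1.18%, 2.96% and 4.53% without ka120 ndr1 replicates 1, 2 and 3; DESeq2 gave 15.7%.

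**Figure D4:**
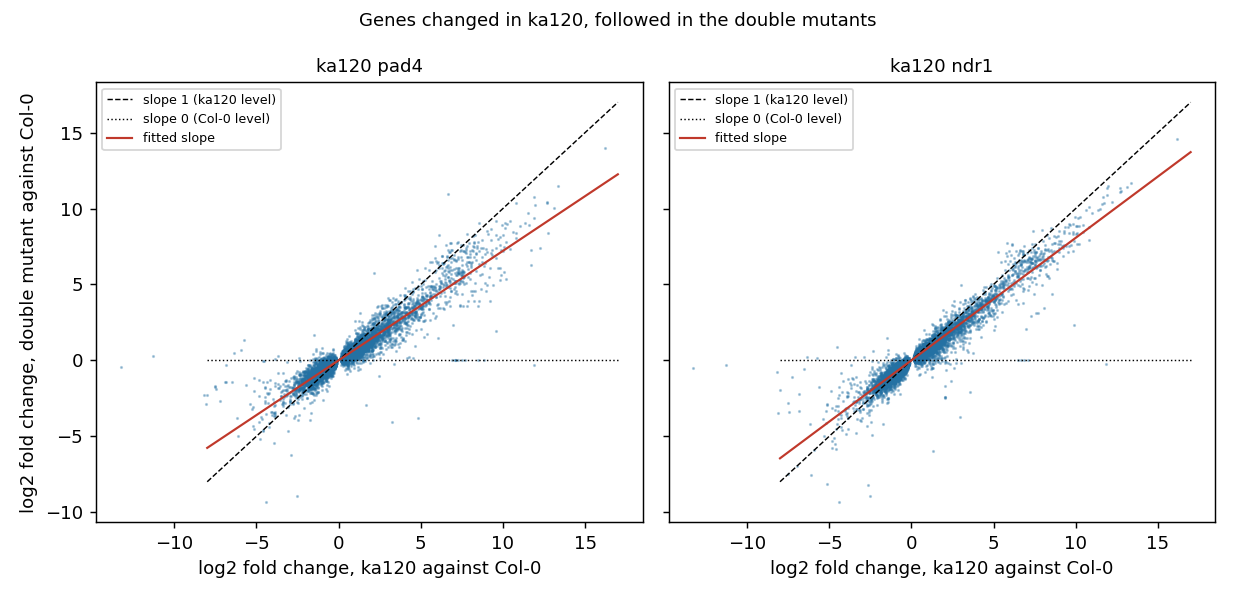
Log2 fold change against Col-0 of each ka120-changed gene in ka120 (horizontal axis) and in each double mutant (vertical axis), with 1 point per gene and the line of the fitted slope. The slopes were 0.721 for ka120 pad4 and 0.807 for ka120 ndr1.

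The direct comparison of the 2 double mutants shares no library with ka120 against Col-0. Among the 8 largest increases, NDR1 (6.40 ± 0.43, adjusted p = 5.63e-05), MYB90 and MAF5 had a symbol and 5 had none, and among the 8 largest decreases 2 had none. MYB90 had 6.03 ± 2.79 CPM in ka120 pad4 and 0.974 ± 0.445 in ka120 ndr1 (2.62 ± 0.42, adjusted p = 0.00903), and MAF5 13.3 ± 1.2 and 2.46 ± 0.753 (2.44 ± 0.20, adjusted p = 2.32e-04). ARD3 was lower in ka120 pad4, with 10.6 ± 10.6 against 74.6 ± 26.9 CPM (-2.81 ± 0.53, adjusted p = 0.0206), as were QQS, a gene of starch metabolism (-2.15 ± 0.26), CRK13 (-2.07 ± 0.34), PAD4 (-1.97 ± 0.31), XTH15 (-1.70 ± 0.28) and CRK37 (-1.69 ± 0.40). PR1 and DMR6 did not pass (adjusted p = 0.442 and 0.0836). Without ka120 pad4 replicate 3 the calls of ARD3 (0.0793), CRK13 (0.0542), PAD4 (0.0532) and CRK37 (0.168) ended. Without ka120 ndr1 replicate 2 those of ARD3 (0.0767) and CRK37 (0.175) did, and CRK37 also lost its call without ka120 pad4 replicate 1 (0.103) and without ka120 ndr1 replicate 1 (0.0649) or 3 (0.0785). CRK37 did not pass with no filter (0.0568) or with counts thinned to the smallest total (0.0534) either. A fit to only these 2 groups ended the calls of MYB90 (0.0554), ARD3 (0.108), CRK13 (0.0613), PAD4 (0.0554), XTH15 (0.059) and CRK37 (0.135).

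Anthocyanin genes were higher in ka120 pad4 in 10 of 15 cases and 14 adjusted over the list alone, including PAP1 (AT1G56650, 1.39 ± 0.33), DFR (1.14 ± 0.16), TT4 (0.96 ± 0.16) and F3H (0.84 ± 0.13). The list had adjusted p = 1.32e-13 by camera and adjusted p = 0.43 with an estimated correlation. Of 21 cell cycle genes, 4 were lower and 9 adjusted over the list alone, MCM4 (-0.43 ± 0.07), MCM5, PCNA1 and PRL (MCM7) (camera adjusted p = 3.16e-04, adjusted p = 0.43 with an estimated correlation). Of 24 SA genes 0 passed over all genes, and 6 were lower adjusted over the list alone (camera adjusted p = 6.97e-06, adjusted p = 0.43 with an estimated correlation). NLR receptors also had 0 over all genes and 5 lower adjusted over the list alone (camera adjusted p = 6.97e-06, adjusted p = 0.43 with an estimated correlation). Among aliphatic glucosinolate genes MYB28 alone was higher over all genes (0.45 ± 0.08) and 10 adjusted over the list alone (camera adjusted p = 5.49e-05, adjusted p = 0.43 with an estimated correlation). Of the pathogenesis-related and SA marker genes, the pathogenesis-related HCHIB (PR3, 1.34 ± 0.30) and PR4 (1.09 ± 0.23) were higher, and 3 were higher and 3 lower adjusted over the list alone (camera adjusted p = 0.188). COR15A (2.60 ± 0.61) and COR47 (0.43 ± 0.10) of the abscisic acid list were higher, BON3 was lower (-1.13 ± 0.25), and the abscisic acid, negative regulator, ER folding, jasmonate, pattern-triggered immunity and heat shock lists passed camera (adjusted p from 6.72e-04 to 0.0421) and lost it (adjusted p = 0.43 to 0.566 with an estimated correlation).

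Between the double mutants 535 genes differed, 337 higher and 198 lower in ka120 pad4, with 4012 at an unadjusted p under 0.05. Of the 417 that had also changed in ka120, 159 were higher there, of which 111 were lower in ka120 pad4 than in ka120 ndr1, and 258 were lower there, of which 226 were higher in ka120 pad4. The 535 became 934 without ka120 pad4 replicate 2, 150 without ka120 pad4 replicate 3, and 263, 152 and 306 without ka120 ndr1 replicates 1, 2 and 3; a fit to only these 2 groups gave 76 and DESeq2 gave 1495. The 417 became 271 and 257 without Col-0 replicates 1 and 3, 239 without ka120 replicate 1, 803 and 119 without ka120 pad4 replicates 2 and 3, and 208, 123 and 228 without ka120 ndr1 replicates 1, 2 and 3; DESeq2 gave 1142.

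**Figure D5:**
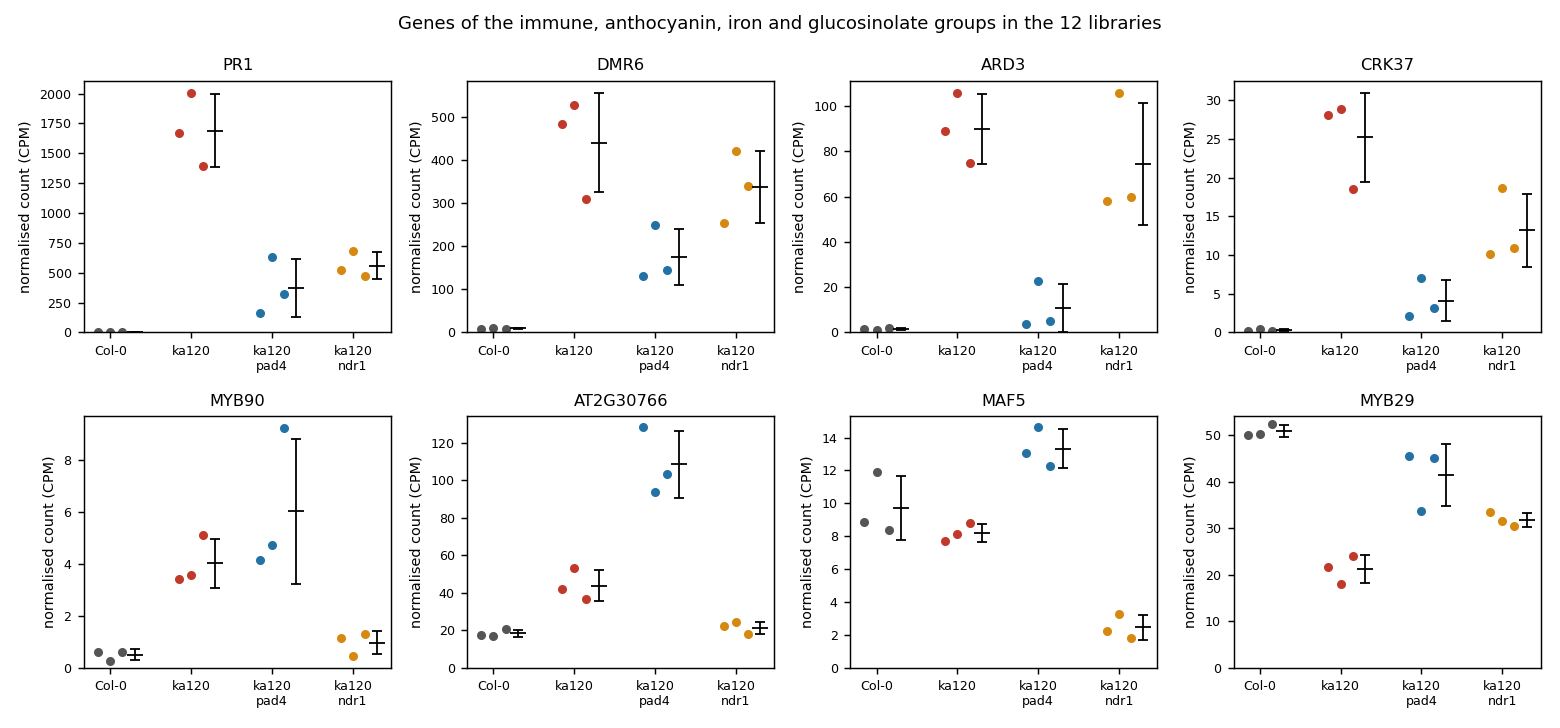
Normalised counts (CPM, vertical axes) of 8 genes in the 4 genotypes, with 1 point per library and the mean ± SD of 3 libraries beside the points. PR1, DMR6, ARD3 and CRK37 were higher in ka120 than in Col-0, and MAF5 was lowest in ka120 ndr1 at a mean of 2.46 CPM.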

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

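The iron list was chosen only after 5 iron-regulated genes had been seen among the called genes. Its test used the 11 other members, whose values had not been looked at. They were tested in the same libraries and comparison as those 5, and genes of 1 response can move together, so the test is not independent of the choice. The double mutants differed from each other by the test of that difference in 535 genes, with 337 higher and 198 lower in ka120 pad4. The 6 libraries make only 10 splits into 3 and 3, too few for a share under 0.05; a fit to these 2 groups called 76 genes in the real split and 1 at most in any other.

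The added mutations moved 8 genes in opposite directions from ka120 by calls in both comparisons, all 8 higher in ka120 pad4 and lower in ka120 ndr1, and 0 the other way round. Independent lists would share 60 in either case. In the same direction 508 genes were called higher and 373 lower in both, against 70 and 51 for independent lists. Both comparisons share the ka120 libraries, and draws at the ka120 level called a mean of 0.1 genes in ka120 pad4 and 0 in ka120 ndr1. These draws treated each double mutant separately, so how far the shared libraries changed the overlaps was not tested. The changes were 1.31 in ka120 pad4 and -1.03 in ka120 ndr1 for AT2G30766, 1.01 and -0.94 for AT5G05250, 0.53 and -0.46 for PYE, a regulator of iron responses, and 0.70 and -1.74 for MAF5. They were 1.13 and -0.81 for AT1G31690, 0.55 and -0.61 for AT5G60270, 0.42 and -0.38 for AT5G41460 and 0.35 and -0.37 for AST56, a sulfate transporter gene (log2, n = 3).

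Genes of the iron-deficiency response were higher in ka120 pad4 than in ka120 ndr1. Of the 11 members not seen beforehand, 7 were called higher, among them PYE (0.99), ZIF1 (1.19), OPT3 (0.77) and BTS (0.65), with camera p = 5.7e-13, and p = 0.00774 with an estimated correlation. Also among the 7, bHLH39 and BHLH100 were near the floor, at 1.46 ± 1.59 and 3.31 ± 2.38 CPM in ka120 pad4 and 0 in ka120 ndr1. FER4, a ferritin made when iron is ample, was lower (-0.73, adjusted p = 0.00705), while FER1 (adjusted p = 0.0819) and FER3 (0.199) did not pass. A single aberrant library was argued against, since leaving out any 1 of the 6 libraries left the median of the 11 at 0.915 or more, against 0.989, although the called members dropped to 5 without ka120 pad4 replicate 1 or 3 or ka120 ndr1 replicate 3, and to 4 without ka120 ndr1 replicate 1 or 2. A difference in iron supply or in the soil between the genotypes' plants may lie behind the pattern as well as the genotypes themselves, and neither was tested. It is therefore a hypothesis that the genotypes differ in their iron response.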

How the results depend on the processing

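Counts divided by 4, genes that drop out left out, and slopes without genes that had no count in a genotype (0.704 and 0.788) were the tests of this part that were added only after the data had been seen. The 6 counts of changed genes stayed within 1.5 times of their values under RLE and upper quartile factors, both filters, organelle genes left out, thinning to the smallest total, counts divided by 4 and genes that drop out left out, and no scaling moved the share of higher genes by more than 10 points. With a threshold of at least 2-fold they were 4060, 661, 207, 2482, 3117 and 97, in the order ka120 against Col-0, ka120 pad4 and ka120 ndr1 against ka120, the same 2 against Col-0, and the double mutants against each other, and the shares moved back were 13.7% and 3.97%. Fewer genes pass a stricter threshold by its construction. DESeq2 gave 2576 for ka120 ndr1 against ka120, 1495 between the double mutants, 1142 in place of 417, and 15.7% in place of 8.35%; a fit to only the 2 groups gave 2634 for ka120 pad4 against ka120 and 76 between the double mutants, with fewer residual degrees of freedom. At least 2-fold left 59 of the 417. The cause was not tested for DESeq2.

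The lists called numbered 10, 10, 11, 10, 10 and 11, and 0 in all 6 comparisons with an estimated correlation. With fry, 15 were called for ka120 against Col-0, 12 for ka120 pad4 against ka120 and 14 for ka120 pad4 against Col-0. It called 1 for ka120 ndr1 against ka120 and 1 between the double mutants. For ka120 ndr1 against Col-0 the highest count under any of the settings was 15. Unlike camera, fry does not compare a list with the other genes.

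Leaving out 1 library gave 10679 to 11713 changed genes for ka120 against Col-0, 1885 to 4764 for ka120 pad4 against ka120, 136 to 2232 for ka120 ndr1 against ka120, 8138 to 8898 and 9486 to 9762 for the double mutants against Col-0, and 150 to 934 between them. The lists called ran from 10 to 11, 10 to 12, 9 to 13, 10 to 10, 9 to 10 and 7 to 12. The shares moved back ran from 15.1% to 33.7% and from 0.918% to 15.6%, the slopes from 0.663 to 0.739 and from 0.757 to 0.821, and the 417 from 119 to 803. Both highest shares were reached without ka120 replicate 3. That library stood at 51.32 on the first principal component, nearer the double mutants than ka120 replicates 1 and 2 at 70.92 and 75.16. The cause of these ranges was not tested.

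The replicate number as a block gave 12168, 4252, 1344, 9346, 10747 and 609 changed genes, shares of 29.8% and 8.6%, slopes of 0.713 and 0.804, and 496 in place of 417. No clear pairing by number was seen: residuals of the same number correlated at -0.055 to 0.11 and of other numbers at -0.13 to 0.16, and 6 of 12 libraries correlated best with their own number. These correlations were not tested against chance, so they cannot exclude a batch shared by libraries of the same number. Of 373 pairs of a named gene and a comparison, 215 were past the threshold, of which 53 lost the call under some alternative and 0 reversed. Thinning to the smallest total removed few counts, so the effect of a much lower depth was not tested.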

Other observations

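The tests of gene families by symbol, of the 18S features, of clock genes and of the direction of the remaining changes were chosen only after those results had been seen. In ka120 against Col-0, families of at least 10 tested genes with a shared symbol were tested with camera, 138 in all. Symbols were cut at their first digit, so a family can also hold unrelated genes that share its letters. Of 48 receptor-like proteins (RLP), 34 rose and 7 fell (adjusted p = 3.82e-07, adjusted p = 0.482 with an estimated correlation). WRKY transcription factors rose in 34 of 56 cases and fell in 5 (adjusted p = 1.09e-04, adjusted p = 0.675 with an estimated correlation), and NAC factors rose in 28 of 64 and fell in 4 (adjusted p = 0.00113, adjusted p = 0.675 with an estimated correlation). Of 38 cysteine-rich receptor-like kinases (CRK), 22 rose and 5 fell (adjusted p = 3.94e-04, adjusted p = 0.675 with an estimated correlation). All 13 fasciclin-like arabinogalactan proteins (FLA) of the cell wall fell (adjusted p = 3.94e-04, adjusted p = 0.675 with an estimated correlation), as did 14 of 18 genes with a PIP symbol (adjusted p = 3.94e-04, adjusted p = 0.675 with an estimated correlation). PIP is the symbol of plasma membrane aquaporins, but other genes share these letters, so the count does not concern aquaporins alone. Auxin-induced SAUR genes fell in 12 of 15 cases and rose in 2 (adjusted p = 0.00763, adjusted p = 0.675 with an estimated correlation).

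In ka120 pad4 against ka120, 18 CRK genes fell and 4 rose (adjusted p = 2.31e-05, adjusted p = 0.653 with an estimated correlation), 22 RLP genes fell and 2 rose (adjusted p = 2.33e-05, adjusted p = 0.653 with an estimated correlation) and 15 WRKY genes fell and 2 rose (adjusted p = 4.89e-05, adjusted p = 0.653 with an estimated correlation). Of 14 PTAC genes, components of the chloroplast transcription complex, 10 rose (adjusted p = 3.73e-06, adjusted p = 0.653 with an estimated correlation), and of 13 FLA genes 8 did (adjusted p = 7.61e-05, adjusted p = 0.653 with an estimated correlation). Between the double mutants, 4 of 23 glutathione transferases of the GSTU family were higher in ka120 pad4 (adjusted p = 0.00247, adjusted p = 0.659 with an estimated correlation).

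Of 12 libraries, Col-0 replicate 2 held 8 of the genes that had a count of 0 in 1 library and at least 5 CPM in another of the same genotype; there were 15 such genes. AT4G01570 had 15.7 and 15.8 CPM in the other Col-0 libraries and 0 in that one.

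The ka120 libraries held 3 features at a level that no other library reached within 8-fold. AT2G01010, an 18S ribosomal RNA copy, had 418 ± 15.4 CPM in ka120 and a mean of 0.0961 in the other 9 libraries, and ENSRNA049494572 had 0.0785 ± 0.00909 against 647. A different assignment of the same reads to features that share sequence stays open for these 2. They moved in opposite directions, but with AT3G41768 they summed to 0.657 of the mean of the other libraries, and each ka120 sum (1200 to 1270 CPM) lay below each of the others (1490 to 2920), so the 3 features do not account for all of the reads. For AT1G08360 (chromosome 1, 2635939 to 2638004), a ribosomal protein gene with 9.23 ± 0.205 CPM against 273, only its paralogs AT2G27530 and AT5G22440 were checked. With them the sum was 0.61 of the others, and the paralogs stood at 0.901 and 0.915, not above them. These values argue against an assignment of its reads to these 2 paralogs. An assignment to any other feature was not tested and stays open. No biological explanation was tested, and a variant or insertion in the ka120 line that the double mutants lack stays open.

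In ka120 pad4, 9378 genes still differed from Col-0. Calls were not more frequent near the mutated loci: genes within 2 Mb of KA120 or PAD4 were called in 42.1% of cases and others in 42.2% (odds ratio 0.995, 95% confidence interval 0.906 to 1.09, which treats genes as independent). The test covers only effects of linked variation on nearby genes. It cannot decide on a linked variant that changes genes elsewhere. A remainder of the ka120 response was tested with no library shared between the comparisons: genes were called in ka120 pad4 against 2 Col-0 libraries, and their sign was taken in ka120 against the Col-0 library left out. The signs were the same in 96.1%, 96.5% and 96.7% of 7615, 7665 and 7510 genes, against 50% for unrelated signs. The median change in the direction called was 0.612, 0.634 and 0.621 in ka120 pad4 against 0.765, 0.781 and 0.769 in ka120. A remainder needs both. Any other difference between all Col-0 libraries and the mutants' libraries would also give equal signs, so the test cannot tell a remainder from such a difference. A difference in the time of sampling stays open, because the median absolute change of 13 clock genes (0.641) lay at percentile 97.6 of 10000 lists matched on expression, whose median was 0.315. The labels give no time of sampling, and an effect of the mutations on the clock was not tested.

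For the other 5 comparisons, too, 10 splits cannot give a share under 0.05, and 1 of 10, the real one, gave the count reached. A fit to only the 2 groups called 12036 genes for ka120 against Col-0 and at most 1 in another split, 2634 and 2 for ka120 pad4 against ka120, and 1211 and 29 for ka120 ndr1 against ka120. It called 8374 and 2 for ka120 pad4 against Col-0, and 10605 and 0 for ka120 ndr1 against Col-0.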
